A study of Mus musculus with 6 samples.

How the data were processed

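Mesenchymal lung cells of aged mice were measured in 3 control libraries and 3 libraries taken 14 days after bleomycin, grouped by the submitters' labels. The authors deposited raw counts of unique molecular identifiers (UMIs) per gene and barcode, not normalized, in 1 matrix per library. Lungs were minced and digested enzymatically, red cells were lysed and cells were sorted by negative selection, per the labels' protocols. Cell Ranger 1.3.1 and Seurat 3.0.0 are named in the submitters' processing notes. The deposited gene lists carry a feature-type column, which is the layout of later Cell Ranger versions, so the version that called barcodes as cells is not settled here. The genome build and annotation are not given in the sources used here. The labels name 3 control lungs but do not say that each library, in either group, came from a separate animal. Every file held 27998 genes. The 6 matrices held 60740 barcodes, from 4940 to 15563 per library.

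Barcodes with at least 500 genes and at most 10% mitochondrial counts were kept, which left 37862. Doublets were called within each library by similarity to simulated doublets, at an assumed rate of 0.8% per 1000 cells, and 2025 were removed, leaving 35837 cells. Counts were scaled per cell and log-transformed, 2000 variable genes were reduced to 30 principal components, and cells were clustered by the Leiden method on a graph of 20 neighbours at resolution 1 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2). This gave 31 clusters, 2 of them under 20 cells. Clusters were named "like" a cell type from 14 marker lists, and clusters of low UMI counts without their own markers stayed unnamed. Libraries were compared for duplicates by a chi-square test of their counts, which was at least 29.2 per gene within groups, so none was merged. Barcodes found in more than 1 library were counted, and libraries that shared at least 20% of the barcodes of the smaller one with another were taken as 1 set, which held control 3 and the bleomycin libraries.

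Raw counts were summed per library and cell class, for classes with at least 20 cells in every library, since cells are not replicates. Sums were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, robust fit) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences between classes were tested as a class by group interaction with the library as a block. Gene lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated correlation. Of 34 lists, 33 could be tested, and erythroid transcripts had too few measured members. Shares of cells were compared by exact two-sided permutation tests, whose smallest p with 3 against 3 libraries is 0.1. Median fold changes over all genes were -0.01 with TMM, 0.01 with RLE factors and 0.02 with DESeq2 1.42.0, on the log2 scale. Figures were drawn with matplotlib 3.10.9.

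The genes named were chosen by rule. In fibroblast-like cells these were the 10 largest rises and 10 largest falls among genes past the threshold with an average log2 CPM of at least 5 and no overlap between the libraries of the groups, 22 genes fixed in advance, and up to 3 members of each list with the smallest p. Elsewhere they were the 5 largest rises and falls under the same conditions and the same 22 genes, without the overlap condition for interactions. Groups did not overlap for 62.9% of the genes tested in fibroblast-like cells, against 10% by chance. Fold changes of genes with 3 or fewer counts in a group were left out. A few genes that the rule selects are not reported here.

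Each test was tried on simulated counts made from the real means and library sizes, with 200 genes changed. In fibroblast-like sums, 16.7%, 59.7% and 90.2% of genes changed 1.5-, 2- and 4-fold were recovered among 14435 genes. In pericyte-like sums the shares were 6.35%, 46.8% and 98.4% among 8527 genes, and in mesothelial-like sums 10.9%, 49.2% and 95.0% among 7910 genes. The summed counts of fibroblast-like cells ranged from 30844089 to 33828945 in control and from 70868371 to 90212742 in bleomycin libraries.

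The groups, tests, gene lists, markers, naming rule and most alternatives were set before the data were examined. Alternatives were RLE factors, DESeq2, no low-count filter, sums thinned to the smallest total, a stricter cell filter (1000 genes, 5% mitochondrial counts), doublets kept, resolution 2, the replicate number as a block and the omission of each library. The peribronchial-like class, the adventitial-like against other fibroblast-like comparison, sex as a covariate, clustering without changed genes for the gene tests, the inclusion of the proliferating cluster, the barcode set as a covariate, the omission of cells with a barcode found in another library and shares among named clusters were added after the data were seen. The alveolar-like class was left out of tests for lack of bleomycin cells.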

Results

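Droplet-based single-cell RNA sequencing had been applied to mesenchymal cells from the lungs of aged C57BL/6 mice, an inbred laboratory strain. The cells were sorted as negative for EPCAM, CD31 and CD45, which are surface proteins of epithelial, endothelial and blood cells. The design set 3 control libraries against 3 libraries taken 14 days after bleomycin, a drug that injures the lung and leads to fibrosis, to examine fibroblast types in aged and injured lungs. The unit was the raw count of unique molecular identifiers (UMIs, each marking 1 captured RNA molecule) per gene and cell barcode. The control libraries held 44871058, 43532032 and 47619852 UMIs and the bleomycin libraries 109371491, 102853860 and 132203191. After filtering, 6186, 3848 and 5046 control cells and 6671, 5771 and 8315 bleomycin cells were used. The median was 5573, 9936 and 7693 UMIs per control cell and 11572, 11296 and 11786 per bleomycin cell. Control 3 and the 3 bleomycin libraries shared 3100 to 5125 barcodes pairwise, while pairs with control 1 or 2 shared 13 to 629. Of the cells used, 35.1% in control 3 and 34.3%, 34.4% and 32.6% in the bleomycin libraries had a barcode also found in another library, against 3.02% and 14.3% in controls 1 and 2. These cells had a median of 1089 UMIs in control 3, against 8945 for its other cells. In bleomycin 1, 2 and 3 the medians were 1175, 9118 and 2207, against 13551.5, 11313 and 11856. In controls 1 and 2 they were deeper, at 16406 and 18965, against 5509 and 9196. The cause was not tested. Control 3 and the bleomycin libraries, called the barcode set here, stand apart from controls 1 and 2, and no bleomycin library lies outside the set. A fit with the set as a covariate therefore rests the group difference on control 3, a lone sample assumed to vary like the others. The labels do not say that every library came from a separate animal, so p-values measure the spread between these libraries, which may in part be technical. Replicate 3 of each group expressed Xist, at 805 and 689 CPM (the count scaled to a common library total) over all cells, against at most 11.2 in the other libraries. Levels are means ± SD of CPM over n = 3 libraries per group unless stated, fold changes are log2 ratios of bleomycin over control ± SE, and "rose" or "fell" is written of genes past an adjusted p of 0.05 in edgeR's quasi-likelihood test. The genome build is not given in the sources used here, so no coordinates are printed.

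Most sorted cells were fibroblast-like in both groups, at 67.1% ± 13.0 (SD, n = 3) of control and 57.4% ± 5.73 of bleomycin cells. A proliferating cluster led by the mitotic genes Ube2c, Birc5 and Mki67 held 3.11% ± 1.02 of bleomycin cells, from 228, 114 and 328 cells per library, against 0.0207% ± 0.00496 of control cells, or 1 cell in each library. Pericyte-like cells made up 5.06% ± 0.707 of control and 1.55% ± 0.310 of bleomycin cells, smooth muscle-like cells 4.56% ± 0.264 and 4.29% ± 0.533, and mesothelial-like cells 2.23% ± 0.932 and 1.24% ± 0.159. The proliferating, pericyte-like and mesothelial-like shares did not overlap between groups, nor did the endothelial-like ones, at 1.35% and 0.485%. For each the exact two-sided permutation test gave p = 0.1 (adjusted p = 0.25 over the classes), and 0.1 is the smallest p that 3 against 3 libraries allow. The sort gate sets which cells could be seen at all, and unnamed clusters, mostly of low UMI counts, held 18.7% ± 12.7 of control and 30.9% ± 5.59 of bleomycin cells. Among named clusters alone, the fibroblast-like difference changed sign, at 82.2% and 82.9%, while the pericyte-like shares were 6.25% and 2.23%. With clusters drawn from genes that did not change, the proliferating shares were 0.0141% and 2.54% and the pericyte-like shares 4.98% and 2.32%. With the stricter cell filter the pericyte-like shares overlapped, at 4.55%, 5.24% and 5.69% of control and 2.34%, 2.09% and 4.75% of bleomycin cells (exact two-sided permutation p = 0.2, adjusted p = 0.25). Within the barcode set, the difference of bleomycin from control 3 was 4.25 percentage points for fibroblast-like, -2.73 for pericyte-like, -2.05 for mesothelial-like and 3.09 for proliferating cells. With cells of shared barcodes left out, the pericyte-like shares were 6.14% and 2.29%, the mesothelial-like shares 1.96% and 1.77% and the smooth muscle-like shares 4.86% and 6.32%, and none of the proliferating control cells remained.

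In fibroblast-like cells, Spp1, Eln and Cthrc1 rose and Slc7a10, Inmt and Tcf21 fell after bleomycin. Spp1 (ENSMUSG00000029304), which encodes the matrix and signalling protein osteopontin, went from 22.4 ± 22.1 to 9696 ± 5100 CPM, a log2 change of 8.76 ± 1.12. Eln (ENSMUSG00000029675), the gene of tropoelastin, rose by 5.44 ± 0.37, from 116 ± 21.2 to 5013 ± 2270 CPM. Cthrc1 (ENSMUSG00000054196), a secreted collagen triple helix repeat protein, rose by 6.80 ± 0.47, from 0.807 ± 0.263 to 89.8 ± 46.1 CPM. Grem1, a secreted antagonist of bone morphogenetic proteins, rose by 7.27 ± 0.66, and Fst, which encodes the activin-binding protein follistatin, by 6.81 ± 0.35. Among the other genes with the strongest rises were Lrg1 (8.55 ± 0.82), Chl1 (7.75 ± 0.25), the epidermal growth factor receptor ligand Ereg (5.58 ± 0.58) and the protease inhibitor Slpi (5.49 ± 0.32).

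The 10 strongest falls in fibroblast-like cells were led by Slc7a10 (ENSMUSG00000030495), a neutral amino acid transporter, with a log2 change of -4.64 ± 0.59, from 92.1 ± 15.8 to 3.68 ± 3.07 CPM. Inmt (ENSMUSG00000003477), an indolethylamine methyltransferase, fell from 6820 ± 648 to 758 ± 267 CPM, a change of -3.17 ± 0.28. Colq changed by -4.55 ± 0.42, Ppl by -3.67 ± 0.40, Faim2 by -3.47 ± 0.42 and Mapt, the gene of tau, by -3.31 ± 0.24. The adrenergic receptor gene Adra1a changed by -3.26 ± 0.26, the sodium channel gene Scn3a by -3.18 ± 0.40, and Selenbp1 and Mettl7a1 each by -3.13. Among genes fixed in advance, the transcription factor Tcf21 changed by -2.64 ± 0.22, the matrix protein Npnt by -1.73 ± 0.24 and Hhip by -1.70 ± 0.57. Smaller falls were seen for Pparg (-0.97 ± 0.23), Pdgfra (-0.72 ± 0.24) and Ebf1 (-0.69 ± 0.21), while Pi16 (-0.61 ± 0.31) and the lipid droplet gene Plin2 (0.34 ± 0.16) did not pass the test. In the cells of the class that were neither adventitial-like nor peribronchial-like, Ebf1 instead rose, by 1.73 ± 0.48, against -0.57 ± 0.14 in adventitial-like cells, though that difference missed the threshold (-2.08 ± 0.60, edgeR, adjusted p = 0.0707). Hhip was at 0.89 ± 0.52 there, which did not pass, against -1.24 ± 0.32 in adventitial-like cells (difference -1.94 ± 0.22). In all, 7404 of 14618 genes tested passed, 3786 higher and 3618 lower. RNA free in the droplets was gauged by the lowest mean CPM among endothelial-, epithelial- and leukocyte-like cells, and 1606 of the rises and 2337 of the falls lay above 3 times that reference. For a gene that these reference cells express themselves, the reference includes their own RNA. The class was held mostly by clusters 1, 3 and 6 in control libraries and by clusters 0, 4, 5 and 10 after bleomycin. By edgeR, Pdgfra missed the threshold without control 1, 2 or 3 or bleomycin 1 or 3 (adjusted p from 0.0732 to 0.102), and Ebf1 without control 1, 2 or 3 or bleomycin 1 or 2 (0.0632 to 0.0854). Hhip missed it without control 1 or 2 or bleomycin 2 or 3 (0.0847 to 0.179) and with DESeq2 (0.0608), and was at -2.62 without bleomycin 1. Ebf1 was at -1.22 with the stricter cell filter, -1.15 at the higher resolution and -1.14 with clusters drawn without changed genes. Without the low-count filter Hhip (edgeR, adjusted p = 0.166) and Pdgfra (0.0551) did not pass. With the barcode set as a covariate 3528 genes passed, 1776 higher and 1752 lower, while Ebf1, Pdgfra, Pparg, Gli1 and Hhip did not (adjusted p from 0.0721 to 0.359). The log2 change of Hhip was -0.97 ± 0.73 in that fit, and those of the other 4 were -0.76 ± 0.30, -0.77 ± 0.34, -0.79 ± 0.33 and -0.86 ± 0.29. With cells of shared barcodes left out Ebf1 was at -0.37 (edgeR, adjusted p = 0.125), Col14a1 at -0.39 (0.0554) and Pdgfra at -0.64 (0.0737), none past the threshold, and Il11 at 2.39.

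**Figure D1:**
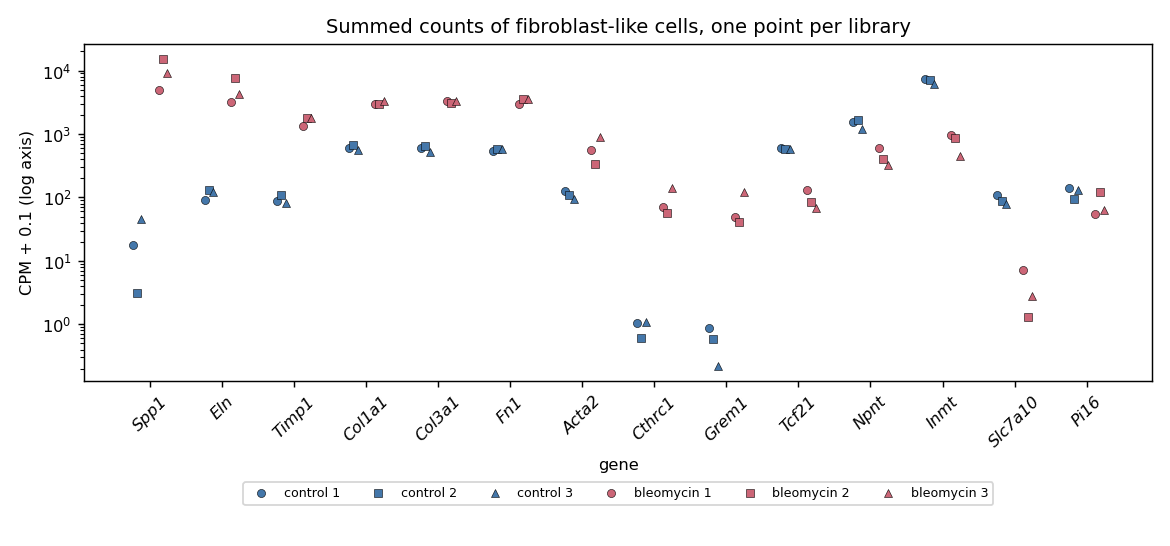
CPM + 0.1 on a log axis for 14 genes in the summed counts of fibroblast-like cells, 1 point for each of the 3 control (blue) and 3 bleomycin (red) libraries. For Spp1, the control mean is 22.4 and the bleomycin mean 9696 CPM, while the libraries of the groups overlap for Pi16.

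Matrix gene lists held rises and falls in fibroblast-like cells. Of 16 fibril-forming and fibril-associated collagens, 14 rose and 2 fell, among them Col1a1 at 2.33 ± 0.11 (607 ± 49.5 to 3061 ± 180 CPM), Col3a1 at 2.45 ± 0.13 and Col5a2 at 3.18 ± 0.12 (camera with a preset correlation of 0.01, adjusted p = 9.41e-12). With an estimated correlation the collagen list had an adjusted p = 0.209. Of 26 matrix glycoproteins and proteoglycans, 17 rose and 5 fell, with Fn1, the fibronectin gene, at 2.57 ± 0.12, Sparc at 2.27 ± 0.12, Fbn1 at 1.83 ± 0.09 and Postn at 4.17 ± 0.43 (adjusted p = 1.19e-07, and adjusted p = 0.108 with an estimated correlation). Of 20 collagen processing and crosslinking genes, 16 rose and 1 fell, with the prolyl hydroxylase genes P4ha3 at 3.07 ± 0.15 and P3h1 at 1.57 ± 0.12 (adjusted p = 1.19e-07, and adjusted p = 0.122 with an estimated correlation). Of 21 matrix proteases and inhibitors, 11 rose and 6 fell, led by Timp1, an inhibitor of metalloproteinases, at 4.13 ± 0.19 (93.9 ± 14.4 to 1645 ± 278 CPM), and Mmp14 at 2.68 ± 0.17 (adjusted p = 0.00706, and adjusted p = 0.29 with an estimated correlation). The basement membrane list had 7 rises, such as Col4a1 at 2.65 ± 0.19 and Lama5 at 2.83 ± 0.22, and 6 falls among 19, and was not called (adjusted p = 0.331).

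Contractile and signalling genes also went both ways in fibroblast-like cells. Of 15 contractile genes 10 rose and 2 fell, with the smooth muscle actin gene Acta2 at 2.44 ± 0.34 (110 ± 15.8 to 595 ± 284 CPM), Tagln at 1.69 ± 0.27 and Tpm1 at 1.82 ± 0.18 (adjusted p = 0.00111, and adjusted p = 0.561 with an estimated correlation). Of 17 genes of the TGF-beta pathway and its targets 10 rose and 3 fell, with Tgfb1 itself at 2.43 ± 0.17 and the transcription factor Runx1 at 2.61 ± 0.14 (adjusted p = 0.000145, and adjusted p = 0.138 with an estimated correlation). Of 19 Wnt ligands and targets 10 rose and 3 fell, among them the secreted Wnt inhibitor Sfrp1 at 2.40 ± 0.10 and Lef1, a transcription factor of the pathway, at 5.29 ± 0.26 (adjusted p = 0.00114, and adjusted p = 0.143 with an estimated correlation). Chemokines and cytokines had 11 rises and 4 falls among 21, with Il11 at 3.67 ± 0.40, Lif at 2.82 ± 0.17 and Ccl8 at 2.47 ± 0.11 (adjusted p = 0.00365, and adjusted p = 0.293 with an estimated correlation). Hyaluronan genes had 6 rises and 2 falls among 11, with the synthase gene Has2 at 1.94 ± 0.31 and the receptor gene Cd44 at 1.10 ± 0.12 (adjusted p = 0.0373, and adjusted p = 0.29 with an estimated correlation). Growth factors and receptors went both ways, with 9 rises and 8 falls among 18, including Igf1 at 2.38 ± 0.21 and Fgfr4 at -2.75 ± 0.28 (adjusted p = 0.762). Acta2 was at 1.51 where clusters were drawn without changed genes.

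Of 14 genes of the alveolar fibroblast program, 13 fell and 0 rose, including Tcf21, Inmt, Fgfr4 and Itga8 at -2.67 ± 0.31 (adjusted p = 1.66e-08, and adjusted p = 0.293 with an estimated correlation). Of 17 immediate-early and heat shock genes known to respond to tissue dissociation, 9 fell and 1 rose, with Egr1 at -1.29 ± 0.16 and Junb at -0.91 ± 0.13 (adjusted p = 0.0143, and adjusted p = 0.733 with an estimated correlation). The adventitial fibroblast program had 1 rise, Igfbp4 at 0.98 ± 0.14, and 4 falls, such as Col14a1 at -0.78 ± 0.16, among 11 genes (adjusted p = 0.292). Complement genes had 4 falls and 0 rises among 8 (adjusted p = 0.0634). Hedgehog genes had 1 rise and 3 falls among 7, including Gli1 at -0.81 ± 0.19 (adjusted p = 0.565), and retinoid metabolism 3 rises and 4 falls among 12, including Aldh1a1 at -1.59 ± 0.19 (adjusted p = 0.638). For the retinoid list the mean (0.13) and median (0.19) lay above 0 while camera gave the direction as down, and for cholesterol synthesis the mean (0.02) and median (-0.12) differed in sign.

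Of 24 cell cycle genes 19 rose and 1 fell in fibroblast-like cells outside the proliferating cluster (adjusted p = 4.13e-05, and adjusted p = 0.512 with an estimated correlation), but Top2a, Cdk1 and Birc5 lay within 3 times the free-RNA reference, at 3.77, 3.98 and 3.68 CPM after bleomycin. With the proliferating cluster included, Top2a was at 5.03 and Birc5 at 5.06. Of 14 senescence genes and secreted senescence factors 9 rose and 3 fell (adjusted p = 0.00245, and adjusted p = 0.29 with an estimated correlation). Among them Cdkn1a, a cyclin-dependent kinase inhibitor, rose by 1.29 ± 0.14, to a level within 3 times the free-RNA reference of 251 CPM. Thinned to 2000 UMIs, 69.9% of control and 51.7% of bleomycin endothelial-like cells held a Cdkn1a UMI. The reference is the lowest mean among the reference cell types, so endothelial-like shares alone do not show whether it holds their own RNA. For Cdkn1a, free RNA was thus not told apart from expression in the reference cells. Cytoplasmic ribosomal protein genes had 52 rises and 1 fall among 78, with Rpl18 at 0.91 ± 0.12 (adjusted p = 4.13e-05, and adjusted p = 0.733 with an estimated correlation). Secretory pathway genes had 15 rises and 3 falls among 26, with Kdelr3 at 1.70 ± 0.13 (adjusted p = 0.00659, and adjusted p = 0.561 with an estimated correlation). Oxidative phosphorylation genes had 11 rises and 1 fall among 18 (adjusted p = 0.017, and adjusted p = 0.697 with an estimated correlation), and glycolysis genes 6 rises and 1 fall among 15 (adjusted p = 0.045, and adjusted p = 0.561 with an estimated correlation). The glycolysis genes Pkm, Eno1 and Gapdh, and the respiratory chain genes Cox5a and Uqcrq, lay within 3 times the free-RNA reference. For these genes too, free RNA was not told apart from expression in the reference cells.

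Several lists were not called in fibroblast-like cells. Fatty acid and lipid droplet genes had 2 rises, led by the lipoprotein lipase gene Lpl at 2.90 ± 0.23, and 4 falls among 18 (adjusted p = 0.565). Cholesterol synthesis had 3 rises and 2 falls among 15 (adjusted p = 0.875), the interferon response 2 rises and 1 fall among 18 (adjusted p = 0.705) and MHC class I presentation 0 rises and 1 fall among 8 (adjusted p = 0.638). BMP genes had 4 rises, with Grem1 and Id1 (2.61 ± 0.30), and 5 falls, with Chrdl1 (-2.85 ± 0.27), among 13 (adjusted p = 0.92). Integrins and adhesion genes had 6 rises and 2 falls among 13 (adjusted p = 0.322), and mitochondrially encoded genes 1 rise and 3 falls among 13 (adjusted p = 0.638). For transcripts of cell types outside the gate, leukocyte genes had 3 rises and 2 falls among 10 (adjusted p = 0.638), with S100a8 at 6.78 ± 5.58 CPM after bleomycin, endothelial genes 1 rise and 1 fall among 6 (adjusted p = 0.836) and epithelial genes 0 rises and 1 fall among 8 (adjusted p = 0.742). In all, 17 of 33 lists were called with the preset correlation and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05. Splits of the libraries that mixed the groups called 0 genes in fibroblast-like cells, but the group difference adds to the spread in such splits. With the preset correlation they still called 4 to 15 lists. A list called at the preset correlation therefore does not by itself show a difference between the groups. The barcode set as a covariate left 15 called, without hyaluronan genes (adjusted p = 0.102) and dissociation genes (0.172). With cells of shared barcodes left out 15 were called, without glycolysis (0.183) and dissociation genes (0.0631). Adjusted over the list alone, the counts of rises and falls became 18 and 5 for matrix glycoproteins, 10 and 3 for senescence, 19 and 2 for cell cycle, and 54 and 2 for ribosomal proteins. They became 7 and 3 for integrins, 4 and 2 for leukocyte transcripts, 1 and 1 for the interferon response and 0 and 3 for mitochondrially encoded genes, and equalled those given for the other lists.

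**Figure D2:**
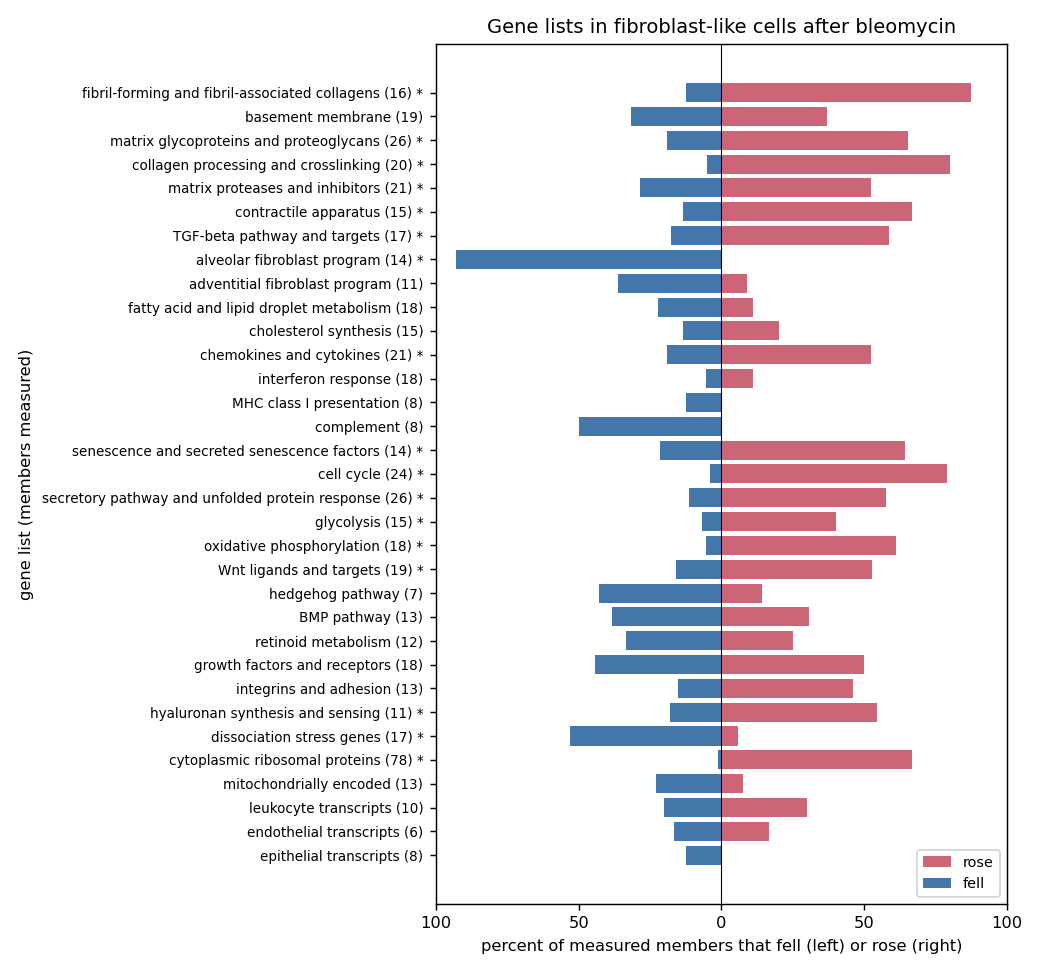
For each of 33 gene lists, the percent of measured members (their number in parentheses) that fell (blue, left) or rose (red, right) in fibroblast-like cells after bleomycin, with lists called by camera at a preset correlation marked by a star. The collagen list has 14 rises among 16 genes and the alveolar fibroblast list 13 falls among 14.

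To compare shares of cells across depths, each fibroblast-like cell was thinned to 2000 UMIs, which left out 166 of 10221 control and 95 of 11998 bleomycin cells. Cthrc1 was then seen in 0.182% ± 0.0388 of control and 7.66% ± 3.71 of bleomycin cells, Postn in 0.785% ± 0.227 and 11.4% ± 5.50, Acta2 in 13.5% ± 1.95 and 29.9% ± 12.5, and Tcf21 in 55.5% ± 1.42 and 15.8% ± 4.04. Endothelial-like cells, of median depth 4019.5 UMIs in 136 control and 5037.5 UMIs in 58 bleomycin cells, gave 4.41% and 0 for Cthrc1, 2.94% and 3.45% for Postn, 5.88% and 10.3% for Acta2, and 6.62% and 1.72% for Tcf21. A share of 0 of these 58 cells allows up to 5.17%. The control share of Postn lay below the endothelial-like one and is not read as expression. For Cthrc1 the endothelial-like control share lay above those of control smooth muscle-like (0.152%) and pericyte-like cells (0 of 667, which allows up to 0.450%). It was not taken as a background level. The fibroblast-like control share of Cthrc1 lay near the smooth muscle-like one and is not read as expression. Spp1 was seen in 1.01% ± 0.432 of control and 49.7% ± 18.0 of bleomycin fibroblast-like cells. In other cells, thinned alike, the control and bleomycin shares of Spp1 were 3.68% and 48.3% (endothelial-like), 2.58% and 28.8% (smooth muscle-like) and 1.39% and 31.9% (adventitial-like). Pericyte-like cells held it in 65.7% of control and 70.1% of bleomycin cells. Cdkn1a was seen in 20.7% and 35.3% of fibroblast-like cells, against 69.9% and 51.7% of endothelial-like, 19.8% and 21.7% of pericyte-like and 31.2% and 33.0% of smooth muscle-like cells. Top2a was seen in 0.111% and 0.620% of fibroblast-like and 0.735% and 5.17% of endothelial-like cells. It was seen in 0 of 658 control and 0 of 879 bleomycin smooth muscle-like cells, which allows up to 0.456% and 0.341%. The Cdkn1a shares of endothelial-like cells, and their Top2a share after bleomycin, lay above those of the other classes and were not taken as a background level. The control share of Top2a lay below the endothelial-like one and is not read as expression. The Spp1 share of fibroblast-like cells lay below the endothelial-like share in control libraries (3.68%) and near it after bleomycin, so neither is read as a share of cells that express it. Pi16 was seen in 10.2% ± 1.47 and 7.32% ± 4.13 (exact two-sided permutation p = 0.4). For the other 7 genes no library of 1 group overlapped the other (exact two-sided permutation p = 0.1, the smallest possible, adjusted p = 0.114 over 8 genes), though with cells of shared barcodes left out Acta2 overlapped (exact permutation p = 0.2). Without thinning the shares were 0.504% and 20.9% for Cthrc1, 2.73% and 27.3% for Postn, 35.7% and 67.7% for Acta2, and 82.1% and 54.8% for Tcf21. They were 4.51% and 89.9% for Spp1, 40.1% and 69.8% for Cdkn1a, 0.413% and 4.53% for Top2a, and 16.1% and 13.1% for Pi16.

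**Figure D3:**
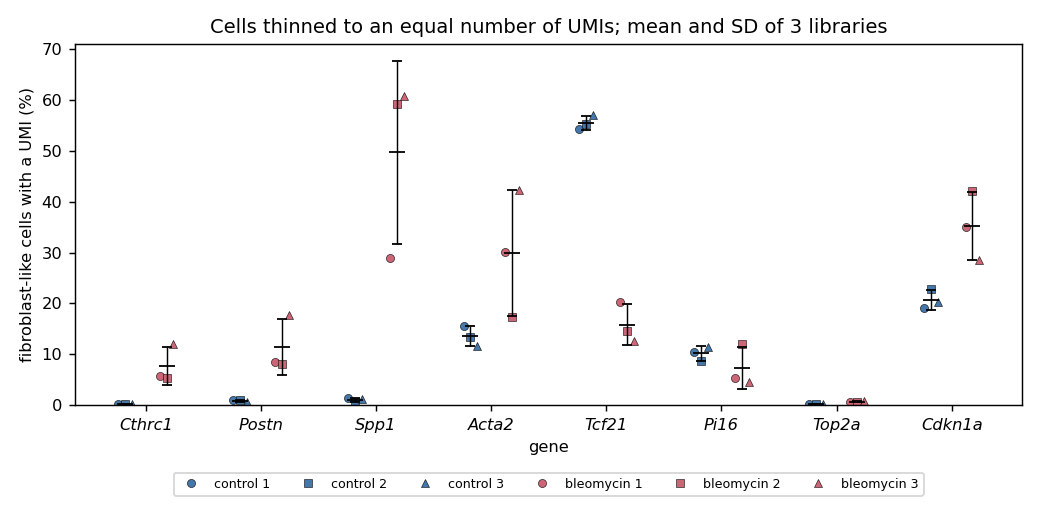
Percent of fibroblast-like cells with at least 1 UMI of each of 8 genes after thinning to 2000 UMIs per cell, 1 point per library, with bars for the mean and SD of 3 libraries per group. The control and bleomycin means are 55.5% and 15.8% for Tcf21 and 0.182% and 7.66% for Cthrc1.

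Adventitial-like fibroblasts, named by markers such as Pi16 that mark the connective tissue sheath around airways and vessels, also raised Col1a1 and Col3a1. Col3a1 rose by 2.43 ± 0.20, Col1a1 by 1.99 ± 0.16, Timp1 by 2.35 ± 0.13 and Postn by 3.05 ± 0.35. Among the strongest rises were the chemokine gene Cxcl13, from 4.30 ± 5.30 to 515 ± 220 CPM (6.91 ± 0.81), Cthrc1 (6.19 ± 1.02), Igfbp2 (6.05 ± 1.22) and the lubricating proteoglycan gene Prg4 (5.21 ± 0.30). Lrg1 had 2 counts in the control sums and 2517 in the bleomycin sums, so no fitted fold is given. The strongest falls were Slc38a5 (-2.65 ± 0.24), Vwa1 (-2.19 ± 0.37), St8sia2 (-2.18 ± 0.23), Frmd4b (-2.14 ± 0.29, within 3 times the free-RNA reference) and Inmt (-2.12 ± 0.34). Acta2 was at 0.29 ± 0.39 and Pi16 at 0.63 ± 0.22, and neither passed. Of 11435 genes tested, 1726 passed, 931 higher and 795 lower, of which 362 and 493 lay above the free-RNA reference. The count was 457, 423 and 772 without control 1, 2 or 3, and 822 without bleomycin 3. By edgeR, Cthrc1 missed the threshold without control 1 or 2 or bleomycin 2 (adjusted p from 0.0527 to 0.0623) and Igfbp2 without control 1, 2 or 3 or bleomycin 2 (0.0628 to 0.0934). Without the low-count filter neither passed (0.0621 and 0.093). A covariate for the barcode set left 83 genes, and Cthrc1, Igfbp2, Postn, Inmt, Vwa1 and Frmd4b no longer passed (edgeR, adjusted p from 0.0689 to 0.204), with log2 changes 0.905 to 0.974 times those without it and SEs 1.27 to 1.61 times as large. Alveolar-like clusters held 56, 3 and 6 bleomycin cells against 2548, 1330 and 1377 control cells, too few for a test within that class. The name rests on markers such as Tcf21, Inmt and Slc7a10, which fell in fibroblast-like cells after bleomycin. Cells that lowered these markers may not have received the name, so fewer such cells and lower markers in them were not told apart.

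Peribronchial-like fibroblasts, which lie around airways and carry the marker Hhip, were tested although the design had not listed them. Fst rose by 7.75 ± 0.36, the acute-phase gene Saa3 by 7.15 ± 0.71, Postn by 6.28 ± 0.70 and Wisp1 by 5.38 ± 0.46, from totals of 7 control counts for Fst, 5 for Saa3 and 7 for Wisp1. Col1a1 rose by 3.63 ± 0.26 and Timp1 by 3.59 ± 0.23, while Spp1 (5.78 ± 0.34) stayed within 3 times the free-RNA reference. Hhip, a hedgehog-binding protein, went from 2988 ± 525 to 470 ± 349 CPM (-2.67 ± 0.58). Aox3 changed by -4.92 ± 0.34, Tcap by -4.46 ± 0.36, Pnmt by -4.04 ± 0.28, Inmt by -3.91 ± 0.23 (control level within 3 times the reference) and the globin gene Ngb by -3.61 ± 0.21. In all 3016 of 9803 genes passed, 1505 higher and 1511 lower, with 529 and 872 above the reference. The class was held by cluster 16, led by Hhip and Pnmt, in control libraries and by cluster 20, led by Pappa2 and Lum, after bleomycin, and the count was 1886 without control 1. By edgeR, Hhip missed the threshold without control 2 (adjusted p = 0.0505) or bleomycin 2 (0.112) or without the low-count filter (0.0625), and Postn was at 4.17 where clusters were drawn without changed genes. A fit with the barcode set as a covariate passed 706 genes but not Hhip (-2.37 ± 0.71, edgeR, adjusted p = 0.123), and Saa3 and Wisp1 had no counts in control 3.

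Pericyte-like cells, which wrap capillaries, raised Csrp2, Tagln and Col1a1, while Acta2 (1.28 ± 0.36), Col3a1 (1.14 ± 0.37), Spp1 and Postn did not pass. Csrp2 rose by 3.13 ± 0.19, from 26.6 ± 5.60 to 233 ± 25.4 CPM, Tagln by 1.15 ± 0.19 and Col1a1 by 1.41 ± 0.17, and the fatty acid-binding protein gene Fabp4 by 3.89 ± 0.74. Spp1 was at 5558 ± 1610 and 6978 ± 7200 CPM (0.33 ± 0.90) and Postn at 2497 ± 285 and 2253 ± 431 (-0.15 ± 0.15). Hp, Timp1 and Fn1 were also among the 5 strongest rises, at 67.9 ± 33.5, 106 ± 35.0 and 548 ± 201 CPM, all within 3 times the free-RNA reference. Mamdc2 fell by 2.28 on the log2 scale, Fam19a1 by -2.13 ± 0.28 and the clock-controlled gene Hlf by -1.99 ± 0.32, with Pcolce2 and Inmt within 3 times the reference. Of 8784 genes tested 1202 passed, 640 higher and 562 lower, with 228 and 386 above the reference. The count was 656, 577 and 655 without control 1, 2 or 3, 1980 without bleomycin 2, 573 without bleomycin 3, 772 after thinning, 1959 with a stricter cell filter, and 2116 and 2070 with clusters drawn at a higher resolution or without changed genes. By edgeR, Fabp4 missed the threshold without control 3 or any bleomycin library (adjusted p from 0.0602 to 0.115), without the low-count filter (0.0725) or with the stricter cell filter (0.0651), Inmt without control 1 or 2 or bleomycin 2 (0.0509 to 0.125) or the low-count filter (0.0691), and Pcolce2 without bleomycin 3 (0.0542). With the stricter filter, the higher resolution and clusters drawn without changed genes, Col1a1 was at 2.55, 2.40 and 2.34. In these settings Pcolce2 was at -0.92, -1.03 and -1.12, against -2.765 as reported, and did not pass. Inmt, at -1.735, -2.095 and -2.063 against -2.661, did not pass either. Tagln was at 0.62 with the stricter filter. When the barcode set was a covariate 94 genes passed, and Tagln, Fabp4, Hp, Hlf, Inmt and Pcolce2 did not (edgeR, adjusted p from 0.0638 to 0.328). Their log2 changes were 0.744 to 1.05 times those without it, and the SEs 0.992 to 1.73 times.

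Smooth muscle-like cells had fewer passing genes, and their contractile anchors did not pass, with Acta2 at -0.48 ± 0.14 and Tagln at -0.05 ± 0.11. Serpina3n, a serine protease inhibitor gene, rose by 3.74 ± 0.54, from 35.4 ± 8.02 to 478 ± 262 CPM, and Ildr2 (1.74 ± 0.18), Fgl2 (1.70 ± 0.21), the cyclophilin gene Ppic (1.69 ± 0.17) and Col1a1 (1.00 ± 0.21) rose less. Timp1 rose to 194 ± 25.9 CPM, within 3 times the free-RNA reference. Ogn, a small leucine-rich proteoglycan gene, changed by -2.98 ± 0.35, Pnmt by -1.96 ± 0.40 and the gap junction gene Gja1 by -1.84 ± 0.32, while Inmt and Pcolce2 lay within 3 times the reference. Of 10312 genes tested 481 passed, 231 higher and 250 lower, with 125 and 170 above the reference. The count was 82, 96 and 273 without control 1, 2 or 3, 818 and 207 without bleomycin 2 or 3, 827 with no low-count filter and 285 with a stricter cell filter. By edgeR, Serpina3n missed the threshold without any library but bleomycin 1 (adjusted p from 0.0535 to 0.119), and Col1a1 without any but bleomycin 2 (0.0668 to 0.136). So did Pnmt without control 1 or 2 or bleomycin 2 or 3 (0.0657 to 0.202), and Gja1 without control 1 or 2 or bleomycin 3 (0.0657 to 0.0923). Inmt missed it without control 2 or bleomycin 1 or 2 (0.0546 to 0.0738) and Ogn without bleomycin 3 (0.0684). Serpina3n also missed it with sex as a covariate (3.76, adjusted p = 0.0597). Without the low-count filter Serpina3n (0.056), Pnmt (0.139), Gja1 (0.0567) and Inmt (0.051) did not pass. Nor did Pnmt in thinned sums (-1.78, adjusted p = 0.0649), with the stricter filter (-0.75, 0.239) or with clusters drawn without changed genes (-0.92, 0.0901). Col1a1 did not pass with the stricter filter (0.0772), nor with doublets kept (0.12), where Inmt (0.0599) and Pcolce2 (0.0562) did not either. Gja1 was at -1.10 with the stricter filter. With the barcode set as a covariate 9 genes passed, and none of the genes named here as rising or falling did except Timp1 (edgeR, adjusted p from 0.0605 to 0.393). Log2 changes of the 10 that ended were 0.674 (Pnmt) to 1.13 (Col1a1) times those without it, and SEs 1.01 to 1.65 times.

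Mesothelial-like cells, which line the lung surface, raised Plac8 by 3.21 ± 0.28, from 24.8 ± 7.31 to 243 ± 71.0 CPM, and Timp1 by 2.75 ± 0.30. Trem2, best known as a receptor of macrophages, rose by 4.08 ± 0.62, from 4.35 ± 3.87 to 98.6 ± 47.6 CPM. Spp1 and Cp rose to 252 ± 122 and 108 ± 45.4 CPM, within 3 times the free-RNA reference. Tcap changed by -4.20 ± 0.42, the clock output gene Dbp by -2.69 ± 0.28, Xpnpep2 by -2.06 ± 0.30 and Rab17 by -1.83 ± 0.25, and Inmt was within 3 times the reference. Of 8137 genes tested 237 passed, 124 higher and 113 lower, with 70 and 92 above the reference. The count was 52, 44 and 65 without control 1, 2 or 3, 502 and 49 without bleomycin 1 or 3, 549 with no low-count filter and 147 with a stricter cell filter. By edgeR, Trem2 missed the threshold without control 1 or 2 or bleomycin 3 (adjusted p from 0.0952 to 0.105), Spp1 without any library but bleomycin 1 (0.0558 to 0.105), Cp without control 2 (0.0524) and Inmt without bleomycin 2 (0.0615). With doublets kept Cp (0.108), Spp1 (0.106) and Inmt (0.243) did not pass, nor did Inmt with the stricter filter (0.061) or Trem2 without the low-count filter (0.0705). With the barcode set as a covariate 35 genes passed, and Trem2, Spp1, Cp and Timp1 did not (edgeR, adjusted p from 0.0593 to 0.201), at 0.844 to 1.11 times their log2 changes without it and 1.07 to 1.59 times the SEs.

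**Figure D4:**
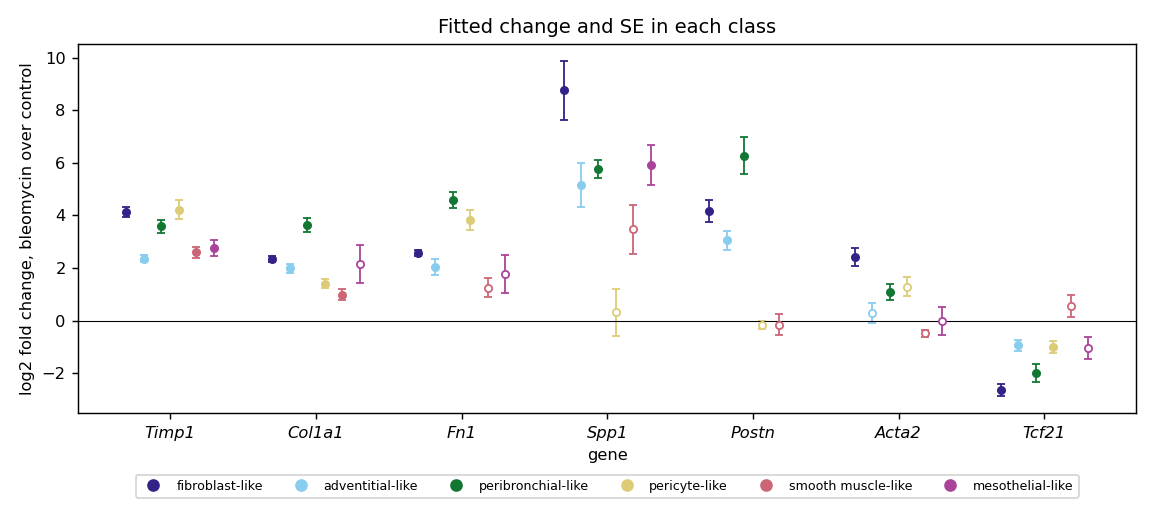
Fitted log2 fold change and SE of 7 genes in 6 cell classes, with filled points past the adjusted threshold and open points not. Timp1 is higher in every class shown, though within 3 times the free-RNA reference in pericyte-like and smooth muscle-like cells, and Spp1 does not pass in pericyte-like (0.33 ± 0.90) or smooth muscle-like cells (3.47 ± 0.94) and lies within 3 times that reference in adventitial-like, peribronchial-like and mesothelial-like cells, as Fn1 does in peribronchial-like and pericyte-like cells.

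Summed over all sorted cells, Cthrc1 (6.45 ± 0.45), Grem1 (6.24 ± 0.53), Chl1 (6.21 ± 0.14), Lrg1 (6.02 ± 0.69) and Spp1 (5.51 ± 0.53) rose most. Slc7a10 (-4.51 ± 0.57), Faim2 (-3.40 ± 0.40), Ppl (-3.27 ± 0.32), Adra1a (-3.14 ± 0.27) and Mapt (-3.08 ± 0.23) fell most. Postn (0.62 ± 0.28), Acta2 (0.17 ± 0.26) and Tagln (0.49 ± 0.21) did not pass in these sums, which mix cell classes. Of 15389 genes tested, 7606 passed, 3954 higher and 3652 lower, with 1642 and 2510 above the free-RNA reference. The barcode set as a covariate left 3733.

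The difference between class responses was tested itself, with the library as a block. Between pericyte-like and fibroblast-like cells, 1672 of 13911 genes responded differently, 896 with the higher log2 change in pericyte-like cells and 776 with the lower. Tgfb1 had the lower change in pericyte-like cells, by a difference of -1.23 ± 0.18, as did Pdgfrb (-1.57 ± 0.19), Acta2 (-1.11 ± 0.17) and Postn (-4.25 ± 0.62). After bleomycin, Tgfb1 lay within 3 times its free-RNA reference of 44.1 CPM in pericyte-like and in adventitial-like cells. Col1a1 differed by -0.89 ± 0.14, but by 0.24, 0.11 and 0.05, none past the threshold, with the stricter cell filter, the higher resolution and clusters drawn without changed genes. The last of these also put Acta2 at -0.31 (edgeR, adjusted p = 0.192). Col3a1 (-1.35 ± 0.43), Timp1 (0.15 ± 0.32) and Tcf21 (1.71 ± 0.46) did not pass that test. The count was 689 after thinning, and without the low-count filter 730 differences were positive and 1145 negative. Postn missed the threshold without control 1 or 3 or bleomycin 2 or 3 (edgeR, adjusted p from 0.0522 to 0.0741), after thinning (0.0581) and with the barcode set as a covariate (-3.68 ± 0.89, 0.194), where 844 genes differed. Between adventitial-like and other fibroblast-like cells, the peribronchial-like left out, a comparison made in place of an alveolar-like one that could not be run, 3469 of 13519 genes differed, 1666 with the higher change in adventitial-like cells. Timp1 had the lower change there, by a difference of -2.05 ± 0.19, as did Tgfb1 (-1.24 ± 0.12), Pdgfrb (-1.70 ± 0.12), Has2 (-2.83 ± 0.40) and Acta2 (-3.05 ± 0.43), and of these Pdgfrb, Has2 and Acta2 did not pass in adventitial-like cells themselves. Tcf21 had the higher change in adventitial-like cells (1.99 ± 0.18). The other fibroblast-like cells included the alveolar-like ones, which came mostly from control libraries. A difference may therefore come from a changed mix of cells among them, which was not tested. The count was 2308 without control 2 and 1290 with the barcode set as a covariate, where Acta2 (-3.34 ± 0.66, edgeR, adjusted p = 0.0684) and Has2 (-2.40 ± 0.57, 0.0579) did not pass.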

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

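The tests of free RNA against fibroblast transcripts were chosen only after the result was seen, as were the adventitial-like comparison, the barcode-set covariate and the extra reference levels. Between pericyte-like and fibroblast-like cells, 1672 genes differed in their response by a test of the difference itself. Spp1 differed most among the genes named, by -9.35 ± 1.08 (edgeR, adjusted p = 0.0103), with a response of 8.76 in fibroblast-like and 0.33 in pericyte-like cells, where it did not pass, and it missed the threshold without control 1 (adjusted p = 0.0521) or bleomycin 3 (0.0576) and with the barcode set as a covariate (-7.95 ± 1.22, 0.0768). Fst differed by -6.06 ± 0.46, with the higher response in fibroblast-like cells. Slpi (-5.58 ± 0.65), Ereg (-5.03 ± 0.54) and Synm (4.11 ± 0.54) also differed, but had too few pericyte-like counts for a response of their own there. Slpi had 14 in control and 8 in bleomycin libraries, under its free-RNA reference of 11.5 CPM after bleomycin, Ereg had 19 and 16, and Synm had 8 and 21. Fgl2 (4.06 ± 0.38), Scn3a (3.73 ± 0.59) and C2 (3.57 ± 0.43) had the higher response in pericyte-like cells, from 16, 22 and 22 control counts there, and Scn3a did not pass in that class, though with doublets kept Scn3a was at 1.87 (edgeR, adjusted p = 0.495) and Synm at 1.97, and Synm was at 6.39 with the stricter filter.

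Between adventitial-like and other fibroblast-like cells, 3469 genes differed. The other cells included the alveolar-like ones, mostly from control libraries, so a changed mix of cells among them stays open. Cxcl13, which encodes a chemokine that attracts B cells, had the higher response in adventitial-like cells by 6.21 ± 0.47, with 6.91 there and 0.76, not past the threshold, in the others. Wisp2 changed by 2.37 in adventitial-like cells and -1.32 in the others, a difference of 3.65 ± 0.46. Tnxb (3.29 ± 0.40), Faim2 (3.04 ± 0.14) and Ppl (2.91 ± 0.13) were lower in both, at -0.57, -1.11 (not past the threshold) and -1.43 in adventitial-like cells against -3.68, -4.09 and -4.32 in the others. Fst (-5.04 ± 0.58), Ereg (-4.91 ± 0.86), Thbs2 (-4.61 ± 0.46), Cd248 (-4.40 ± 0.22) and Penk (-3.74 ± 0.52) had the higher response in the other fibroblast-like cells, and Ereg missed the threshold without bleomycin 3 (edgeR, adjusted p = 0.0516). With the barcode set as a covariate Wisp2 (3.69 ± 0.76), Tnxb (3.33 ± 0.64) and Penk (-4.07 ± 0.92) missed it (edgeR, adjusted p from 0.0661 to 0.102), with SEs 1.62 to 1.77 times those without it.

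Genes called higher in pericyte-like, smooth muscle-like and mesothelial-like cells may in part be RNA released by other cells. Of these genes, 64.4%, 45.9% and 43.6% lay within 3 times the free-RNA reference, but so did 57.6% of the rises in fibroblast-like cells, so this measure did not separate released from own RNA and the explanation cannot be told apart. Among fibroblast transcripts, those at least 10 times the reference in fibroblast-like cells, 9.20% (15 of 163) of the rises in pericyte-like cells lay within 3 times the reference. With other references the shares were 13.3%, 14.1% and 17.9%, under the bound of 20%. The shares were 14.6% (12 of 82) in smooth muscle-like and 17.6% (9 of 51) in mesothelial-like cells, but up to 30.6% and 31.2% with other references, above the bound of 20%, so the question stays open there. The same reference picked these transcripts and measured them, which favours small shares, so free fibroblast RNA is not ruled out in pericyte-like cells either. Fibroblast RNA from doublets, or from fibroblasts placed in these classes, was not tested. Col1a1 in pericyte-like cells was at 2.55 with the stricter cell filter, against 1.41. A response of the cells themselves stays open in all 3 classes.

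With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. In each comparison 1 of 10 splits, the real one, gave as large a result. A split that mixes the groups counts their difference as spread within its sides, so few genes called there do not give a rate of false calls. The real split called 7404 genes in fibroblast-like, 1726 in adventitial-like, 3016 in peribronchial-like, 1202 in pericyte-like, 481 in smooth muscle-like and 237 in mesothelial-like cells, 7606 over all sorted cells, and 1672 and 3469 in the comparisons of responses, and the highest other split called 0 in each. For gene lists the real split called 17 and the other splits 4 to 15, so list calls at the preset correlation also arose where the groups were mixed.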

How the results depend on the processing

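Sex as a covariate, clustering without changed genes, the proliferating cluster, the barcode set and shared barcodes, and shares among named clusters were chosen after the data were seen. Of the counts of genes, 85 stayed within 1.5 times under other settings and 18 did not. With the barcode set as a covariate, which leaves control 3 alone to stand for the controls, the counts were 3528 for fibroblast-like, 83 for adventitial-like, 94 for pericyte-like, 9 for smooth muscle-like, 35 for mesothelial-like, 3733 for all and 706 for peribronchial-like cells, and 844 and 1290 for the comparisons of responses, where fewer libraries carry the comparison. The other 9 were 772 (thinned sums), 1959 (stricter filter), 2116 (resolution 2) and 2070 (clustering without changed genes) for pericyte-like cells, 827 (no low-count filter) and 285 (stricter filter) for smooth muscle-like cells, 549 and 147 for mesothelial-like cells under the same pair of settings, and 689 (thinned sums) for pericyte-like against fibroblast-like responses, where thinning leaves fewer counts. For the others the cause was not tested. With an estimated correlation 0 of 33 lists were called. Without each library in turn, the counts ranged from 5604 to 8261 (fibroblast-like), 423 to 2418 (adventitial-like), 573 to 1980 (pericyte-like), 82 to 818 (smooth muscle-like), 44 to 502 (mesothelial-like), 5729 to 8485 (all cells), 1886 to 3641 (peribronchial-like), 1227 to 1822 and 2308 to 3679 (the comparisons of responses, pericyte-like first), and 16 to 19 for lists. Without the low-count filter 1274 differences were positive and 2113 negative for adventitial-like responses, and with doublets kept 497 and 867 for pericyte-like ones. The fibroblast-like share, -9.72 points after bleomycin against control, was higher by 0.723 among named clusters and by 4.25 within the barcode set, and the smooth muscle-like share was higher by 2.10 (stricter filter), 0.513 (clustering without changed genes), 0.562 (named clusters) and 1.46 (cells of shared barcodes left out). Leave-one-out differences ranged from -16.7 to -3.91 (fibroblast-like), -3.90 to -3.21 (pericyte-like), -0.539 to -0.00663 (smooth muscle-like), -1.32 to -0.452 (mesothelial-like) and 2.68 to 3.66 (proliferating). Those of the shares with a UMI ranged from 5.34 to 8.65 (Cthrc1), 7.43 to 12.3 (Postn), 43.1 to 59.1 (Spp1), 10.2 to 22.7 (Acta2), -41.9 to -38.1 (Tcf21), -5.21 to -1.44 (Pi16), 0.474 to 0.556 (Top2a) and 11.1 to 17.9 (Cdkn1a). For lists not called, camera's direction changed with median log2 changes of -0.111 (replicate block), -0.0941 (sex) and -0.17 (cells of shared barcodes left out) for cholesterol synthesis, against -0.119 as reported, of 0.0472 (block), 0.107 (sex), 0.113 (with the proliferating cluster) and -0.131 (shared barcodes left out) for BMP genes, against 0.124, and of 0.0736 (barcode set) for mitochondrially encoded genes, against -0.0967, so the median itself changed sign in the last of the BMP results and in the mitochondrial one. Leaving out a library also turned camera's direction, with medians of -0.285 to 0.0383 for cholesterol synthesis, -0.0391 to 0.665 for the interferon response, -0.295 to 0.202 for BMP genes and 0.242 to 0.517 for growth factors, which stayed above 0. Of list results, 228 kept direction and call under other settings, 25 no longer passed, most of them with the estimated correlation, and 3 newly passed, and of named gene results 2256 did, 78 no longer passed and 18 newly passed. Named genes changed sign as follows, each with the cause not tested. The pericyte-like against fibroblast-like difference of Col1a1 was 0.243 (stricter filter), 0.110 (resolution 2) and 0.0525 (clustering without changed genes), and that of Timp1, not called, was -0.528 (doublets kept) and -0.188 to 0.378 without 1 library. Uncalled Spp1 in pericyte-like cells was at -0.246 (replicate block), -0.205 (stricter filter), -0.247 (resolution 2) and -0.176 (clustering without changed genes), and -0.959 to 0.776 without 1 library. Uncalled Tagln in smooth muscle-like cells was at 0.0359 (stricter filter) and -0.103 to 0.0274 without 1 library, and uncalled Acta2 at -0.00192 to 0.656 in adventitial-like and -0.0852 to 0.425 in all cells. Replicate numbers do not pair the libraries: deviations correlated at 0.0299, 0.0195 and 0.231 in fibroblast-like cells, and no class had every pair over 0.1. Replicate 3 matched its own number best in every class but the mesothelial-like, replicate 2 in smooth muscle-like (0.0813) and peribronchial-like (0.0531) and replicate 1 in mesothelial-like cells (0.107). The replicate block gave 7086, 1908, 863, 562, 249, 7135 and 3024 genes for fibroblast-, adventitial-, pericyte-, smooth muscle- and mesothelial-like cells, all cells and peribronchial-like cells, and with it pericyte-like Fabp4 had an adjusted p = 0.0728 (edgeR). The alternatives for alveolar-like cells were not run, since that class had no test. Of 1.5-fold simulated changes, 6.25% (peribronchial-like) to 16.7% (fibroblast-like) were recovered in the tests of a class. The simulation changed 200 genes, fewer than passed in each class in the data. The adjusted threshold is looser where more genes change, so these shares do not give the recovery in the data.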

Other observations

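The tests of sex and of the time of day, the minimum of 20 genes and the shares of control clusters were chosen only after the result was seen. The circadian clock genes given here were chosen after their values were seen and not tested for enrichment. In fibroblast-like cells the output genes Dbp (-2.12), Nr1d1 (-1.78), Nr1d2 (-1.03), Hlf (-1.85), Tef (-1.44), Ciart (-1.72), Per2 (-0.90) and Per3 (-1.04), and the repressor gene Bhlhe41 (-2.60), fell on the log2 scale, while Arntl, a core activator of the clock, rose by 3.41 and Nfil3 by 1.38. Npas2 (1.27), Cry1 (-0.20) and Clock (-0.0018) did not pass.

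A change in the mix of cell types was set against these changes. The median change of the output genes within classes was 0.780 times that over all sorted cells in the median class, and at least 0.511 times in every class, which argues against the mix of classes as the whole cause, though a change of mix within classes stays open. A different time of day at collection may also give such changes. By their medians, output genes were lower and opposite-phase genes higher in 4 of 6 classes. Opposite-phase medians were 1.27 in fibroblast-like, 0.38 in adventitial-like, 0.40 in peribronchial-like and 0.14 in smooth muscle-like cells. They were -0.02 in pericyte-like and -0.36 in mesothelial-like cells, over 3 genes each. Among the 6 classes, opposite-phase genes passed only in fibroblast-like cells, of which the adventitial- and peribronchial-like cells are a part. Collection time is not separable from group, so a different time of day cannot be told apart. A response of the clock to the injury stays open and untested.

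Of the 1921 cells in cluster 5, led by Serpina3m, Lrg1 and Eln, 1722 came from bleomycin 2. A control library under a wrong label was tested by whether bleomycin 2 lay beyond all controls in the direction of the other bleomycin libraries, and 89.6% of 8225 genes did, just short of the 90% set in advance. Control clusters 1, 3 and 6 held 0.361% of its fibroblast-like cells, against 73.7%, 74.1% and 75.0% of those of the controls, which argues against that label. The depth and sex tests rested on fewer than 20 genes. After thinning, the number of genes 4-fold apart from both other bleomycin libraries was 100% of that before, 1 and 1. Before thinning the number was 1 for bleomycin 1 and 3 for bleomycin 3, of 4231 genes. By this measure bleomycin 2 was no further apart than the others. For sex the ratio was 0.857, from 6 and 7 genes. Bleomycin 2 had a median of 19228.5 UMIs per fibroblast-like cell, between bleomycin 1 (19846) and 3 (15775). It had the fewest UMIs of these libraries, so depth cannot be told apart. Xist was at 4.03, 11.2 and 689 CPM in bleomycin 1, 2 and 3. The Y-linked Ddx3y was at 94.6, 102 and 4.84. Sex was thus the same in bleomycin 1 and 2, which argues against it as the reason that cluster 5 came mostly from bleomycin 2. Of 7 glucocorticoid response genes, 6 were higher in bleomycin 2 than in the other bleomycin libraries, by a median log2 ratio of 1.05 against -0.93 and -0.34 in the others. Only 3 of the 7 lay above the control mean, among them Fkbp5 at 106 CPM against 21.6, while Klf9 was at 375 against 492, a comparison made after the result was seen. So such a response and a smaller fall from control levels cannot be told apart.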
